A study of Rattus norvegicus with 8 samples.

How the data were processed

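Gene expression was measured in the hypothalamus of 21-day-old female Sprague-Dawley rats on Affymetrix Rat Gene 1.0 arrays. The 8 arrays form 4 groups of 2: offspring of normally fed mothers given saline (Con-s) or leptin (Con-l), and offspring of calorie-restricted mothers given saline (CR-s) or leptin (CR-l). A design note writes the leptin-treated control group as Con-r, and it was read here as Con-l from the sample titles. Each group holds a replicate A and a replicate B. Per the labels, restricted mothers received 50% fewer calories from gestation day 11 to 21 and after birth, and saline or leptin was given from postnatal day 2 to 8. Sample names can be read as saying that the mothers were treated, and the labels do not state whether an RNA sample pools several animals or litters. The p-values therefore measure only the spread between these 8 samples.

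The authors background-corrected, normalized and summarised the probe signals with RMA in Affymetrix Expression Console, whose version is not given in the sources used here. The deposited values are intensities per probe set on the linear scale, since the brightest probe sets lie far beyond the range of log2 signals. They were log2-transformed before any test, as planned in case the values were linear, and were not normalized again. Of 29215 probe sets, 15633 are listed in the annotation, 15310 of them with 1 gene symbol and 323 with several. Symbols came from the Entrez gene number for 15279 probe sets and from a sequence accession for 6, and 25 kept the symbol of the array annotation. Where a gene had several probe sets (527 genes), the probe set with the highest mean over the 8 arrays was kept, which gave 14506 genes. No filter on dim probe sets was applied. Genes without a uniquely named probe set, such as Lepr and Crhr1, were not analysed here. Genome positions are not used here because no genome build is given for the array.

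All comparisons came from a single limma model with 4 group means over the 8 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes with default settings), with 4 residual degrees of freedom and 3.21 prior degrees of freedom. The tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 14506 genes. Standard errors are the moderated ones of this model. The comparisons were CR-s against Con-s, CR-l against CR-s, Con-l against Con-s, CR-l against Con-s, CR-l against Con-l, the difference between the 2 leptin effects (interaction), the diet difference averaged over both treatments, and the leptin difference averaged over both diets. The averaged comparisons set 4 arrays against 4. The groups, comparisons, gene lists, rule for named genes and most of the settings varied were fixed before the data were examined.

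Gene lists were written from general knowledge: 41 lists with 772 entries, of which 670 were measured. The list named late-maturing neurons below holds genes of the perineuronal matrix and of maturation, and it defines no class of neurons. The 40 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera asks whether the genes of a list moved more in a direction than other genes did. Each call was repeated with the correlation estimated from the data. In that setting camera refers its statistic to the 4 residual degrees of freedom, so its p is larger even without correlation. Values given with an estimated correlation therefore do not measure the role of correlation alone. Members of a list that passed were counted at the adjusted p over all genes and, separately, adjusted over the list alone. An exact permutation test of each list mean over the 35 splits of the 8 arrays into 4 and 4 was added after the data had been seen; its smallest possible p is 0.0286. With 2 arrays against 2, the smallest two-sided exact p is 0.333, so no exact test was used for those comparisons.

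Genes were named by this rule: 16 energy-balance genes whatever their result (15 measured); in each comparison the 10 largest rises and 10 largest falls among genes that passed, filled up to 5 per direction with the smallest unadjusted p among genes changed at least 1.5-fold where fewer than 5 passed; and up to 4 members with the smallest unadjusted p of each called list. Cirbp was named as the test of a hypothesis set after the rise of Rbm3 was seen. Any other gene was chosen after its values were seen: Bmp4, Padi2, Pnpla2, Gfap, Serpinh1, Erbb3, Mbp, Mog, Ttr and Slc13a4 in the averaged diet comparison.

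To estimate without shared arrays how much of the diet effect under saline was present under leptin, the covariance across genes of CR-s minus Con-s with CR-l minus Con-l was divided by the covariance of single-array estimates of CR-s minus Con-s. A second ratio with the same denominator measures how far CR-l minus CR-s runs against the diet effect, using different CR-s arrays in its terms. These ratios carry no p-value. A further test was added after the data had been seen: limma's fry on the genes that passed in the averaged diet comparison, each signed by its diet difference.

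The model was tested on simulated data made with normal noise at the moderated spread of each gene. Among 14506 genes in 20 runs, it called 75.6% of changes of 0.5 and 98.2% of changes of 1 on the log2 scale in CR-s against Con-s, and 94.5% and 99.6% in the averaged diet comparison, with a mean of 9.2 and 10.4 unchanged genes called. No leptin effect was simulated there, and a mean of 0.15 genes was called for averaged leptin. The shares of changes called hold for that simulated noise and are no estimate of power in the real arrays. In CR-s against Con-s real differences beyond 1, such as that of Rbm3, did not pass. A planted list of 20 genes shifted by -0.3 was called in 20 of 20 runs. The simulated noise was independent between genes, so these runs do not test list calls where genes are correlated. The first ratio averaged 0.997 when the effect was kept under leptin and 0.498 when it was reduced by 0.5 of its size.

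The settings varied were a replicate block, array weights, eBayes with trend and robust settings (for camera, its variance trend), cyclic loess between arrays, all 29215 probe sets, the upper 60 percent of genes by mean, models with only the compared groups or factor, an estimated correlation for lists, and leaving out each array in turn, where the lone array of a group is assumed to vary like the others. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading the values and drawing. Probe sets without a unique symbol (13905) entered no comparison, except in the alternative with all probe sets and in a separate count.

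Array medians lay between 111.8 and 114.1 intensity units. The number of arrays, 2 per group, limits the precision.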

Results

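Hypothalamic RNA from 21-day-old female offspring was profiled on 8 arrays, 2 for each combination of maternal diet (control or calorie-restricted) and early postnatal treatment (saline or leptin). Leptin is the adipose hormone that acts on hypothalamic neurons to lower food intake. Median intensities ranged from 111.8 to 114.1 between arrays, and the replicates of a group correlated at 0.995 across probe sets, which are not independent replicates. Arrays of different groups correlated almost as highly: the lowest correlation of each array with any other was 0.9938 to 0.9947. For CR-s replicate A the lowest was that with its own replicate. The median absolute difference between replicates was 0.08 on the log2 scale in Con-s, 0.09 in Con-l, 0.09 in CR-s and 0.08 in CR-l. On the first principal component (28.1% of the variance) all Con arrays lay between -9.23 and -4.71 and all CR arrays between 5.25 and 10.1. CR-s replicate B had the narrowest interquartile range, 2.92 on the log2 scale, where the other arrays had 3.01 to 3.08. It also stood apart on the second component (17.3%), at -14.0 where the other arrays lay between -2.88 and 5.37.

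Averaged over saline and leptin, the question was how the hypothalamus of restricted offspring differed from that of controls (4 arrays against 4). Npy and Agrp, which encode the appetite-raising peptides of arcuate neurons, rose 1.69-fold (log2 0.75, SE 0.10, adjusted p = 0.0229) and 1.62-fold (log2 0.70, SE 0.09, adjusted p = 0.0233). Oxt, the gene of oxytocin, fell 1.30-fold (log2 -0.38, SE 0.07, adjusted p = 0.0496). Pomc and Cartpt, whose peptides lower food intake, differed by -0.18 (SE 0.05, adjusted p = 0.161) and -0.22 (SE 0.06, adjusted p = 0.145) and did not pass. Rbm3, a cold-inducible RNA-binding protein, rose 2.64-fold (log2 1.40, SE 0.10, adjusted p = 0.00977), and Ptgds, a prostaglandin D synthase made by meninges and oligodendrocytes, fell 2.92-fold (log2 -1.54, SE 0.13, adjusted p = 0.0133).

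In this averaged comparison 175 genes passed, 47 higher and 128 lower in restricted offspring, with a median absolute log2 difference of 0.40. At an unadjusted p under 0.05 there were 2285 genes, where chance would give 725. Besides Rbm3, Npy and Agrp, the largest rises were F2rl2 (log2 0.80, SE 0.10), Mt2A (0.78, SE 0.13), the thiamine transporter Slc19a3 (0.73, SE 0.09), Zbtb16 (0.72, SE 0.08), Gsta1 (0.69, SE 0.11), Fkbp5 (0.64, SE 0.09) and Hif3a (0.62, SE 0.09). Besides Ptgds, the largest falls were the lipoxygenase Alox15 (-1.52, SE 0.14), the haemoglobin-related Ahsp (-1.46, SE 0.18), Hbb-b1 (-1.42, SE 0.17) and Hbb (-1.29, SE 0.19), Ogn (-1.21, SE 0.13), Kcnj13 (-1.17, SE 0.14), Alas2 (-1.17, SE 0.14), Cdh19 (-0.97, SE 0.09) and Klk6 (-0.97, SE 0.13). The CR and Con arrays did not overlap in 1622 of all 14506 genes, where chance gives 2.86% of genes. Genes are not independent of each other, so this count carries no test. Of the 175 genes, 46 lay in a gene list and 129 in none. Without 1 array the count was 27 (CR-l replicate A), 26 (Con-l replicate B), 15 (CR-l replicate B), 15 (CR-s replicate B), 10 (Con-l replicate A), 4 (CR-s replicate A), 4 (Con-s replicate A) and 0 (Con-s replicate B), with all 175 directions kept each time. The choice of these genes on the same arrays favours kept directions, so those do not show stability. With all 29215 probe sets tested together no gene passed (limma, smallest adjusted p 0.056, 3354 at an unadjusted p under 0.05). With trend and robust settings 744 passed, with the upper 60 percent of genes by mean 609, with the compared factor alone 267, and with the replicate letters as a block 87.

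**Figure D1:**
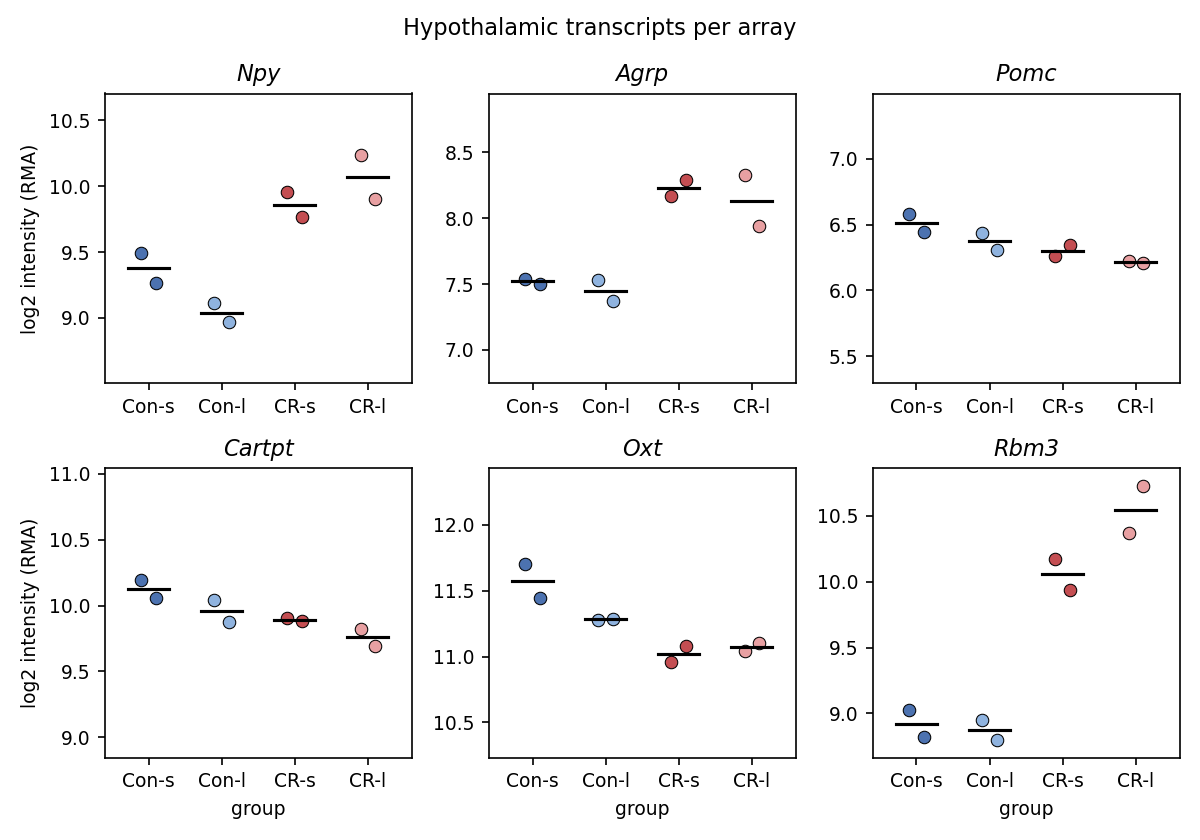
Log2 RMA intensity of 6 transcripts in each array (points) with the mean of each group (lines, n = 2). Npy, Agrp and Rbm3 were higher and Oxt lower in all 4 CR arrays than in all 4 Con arrays, while Pomc and Cartpt did not pass the test.

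Genes of myelin and mature oligodendrocytes were lower together in restricted offspring. All 21 measured members were lower (mean log2 -0.36, camera adjusted p = 5.16e-20, adjusted p = 0.263 with an estimated correlation), 9 of them passing over all genes and 20 adjusted over the list alone. Examples are Enpp2 (autotaxin), which fell 1.70-fold (log2 -0.76, SE 0.06), Ndrg1 (-0.62, SE 0.08), Ermn (-0.54, SE 0.06) and Apod (-0.48, SE 0.06). Mbp, the gene of myelin basic protein, differed by -0.15 (SE 0.04, adjusted p = 0.167) and Mog by -0.27 (SE 0.06, adjusted p = 0.109), and neither passed. Of 18 genes of cholesterol synthesis and uptake 17 were lower (mean -0.24, camera adjusted p = 1.64e-13, adjusted p = 0.309 with an estimated correlation), 5 passing over all genes and 14 adjusted over the list alone. Msmo1 (-0.47, SE 0.05), Cyp51 (-0.43, SE 0.05) and Dhcr7 (-0.40, SE 0.05), enzymes of the late pathway, fell, as did Srebf2 (-0.30, SE 0.04), the transcription factor that drives it. Oligodendrocyte precursor genes were lower too (9 of 11, mean -0.18, median -0.14, camera adjusted p = 0.0138, adjusted p = 0.669 with an estimated correlation), with none passing over all genes and 2 adjusted over the list alone. Olig1 (-0.20) and Vcan (-0.16) had the smallest p, while the mean leaned on Bmp4 (-1.09, SE 0.48, adjusted p = 0.332), which measured 7.01 ± 1.68 (SD, n = 2) in CR-l. Without CR-l replicate A the precursor list had a mean of -0.09 (adjusted p = 0.157) and was not called, nor was it without CR-s replicate A (adjusted p = 0.107) or Con-l replicate B (adjusted p = 0.0633).

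Markers of tissue other than neurons and glia were lower beside these lists. All 8 red blood cell genes were lower (mean log2 -0.78, camera adjusted p = 1.77e-07, adjusted p = 0.263 with an estimated correlation), 5 passing over all genes and 5 adjusted over the list alone, Slc4a1 among them (-0.70, SE 0.09). All 15 genes of meningeal cells were lower (mean -0.47, camera adjusted p = 1.64e-13, adjusted p = 0.321 with an estimated correlation), 5 passing over all genes and 12 adjusted over the list alone, including Slc6a13 (-0.60, SE 0.09) and Col1a2 (-0.32, SE 0.05). Of 18 genes of vessel cells 15 were lower (mean -0.12, camera adjusted p = 0.000125, adjusted p = 0.474 with an estimated correlation), 2 passing over all genes and 5 adjusted over the list alone: Rgs5 (-0.38, SE 0.05) and Tagln (-0.35, SE 0.04), markers of mural cells, passed. The choroid plexus list was not called (mean -0.09, adjusted p = 0.567), with Kcnj13 lower, as given, and Ttr, its most typical transcript, at 0.04 (SE 0.14, adjusted p = 0.912).

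Genes known to rise with glucocorticoids were higher in restricted offspring, 16 of 17 (mean log2 0.33, camera adjusted p = 2.57e-13, adjusted p = 0.263 with an estimated correlation), 6 passing over all genes and 13 adjusted over the list alone. Zbtb16, Fkbp5 (a co-chaperone of the glucocorticoid receptor), the metallothionein Mt1 (0.54, SE 0.08) and the kinase Sgk1 (0.49, SE 0.07) rose. In the peptide lists Npy and Agrp were the members that passed among 12 genes raising food intake (camera adjusted p = 0.408, mean 0.10, median -0.00), and Oxt among 16 lowering it (camera adjusted p = 0.86, a test pointing up beside a mean of -0.00). Adjusted over the list alone the first had 2 higher and the second 2 higher and 3 lower. For the myelin, cholesterol, glucocorticoid, meningeal, red blood cell and vessel lists the exact permutation p over the 35 splits was 0.0286, the smallest possible, with an adjusted p of 0.0817. This p was shared by 14 of the 40 lists, among them the astrocyte, choroid plexus and thyroid hormone lists that camera did not call. Among lists that camera called, it was 0.0571 for the circadian clock (exact permutation adjusted p = 0.134) and 0.0857 for energy-balance receptors, interferon response and oligodendrocyte precursors (exact permutation adjusted p = 0.163 each). Each of the 6 lists named first was called without any single array.

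**Figure D2:**
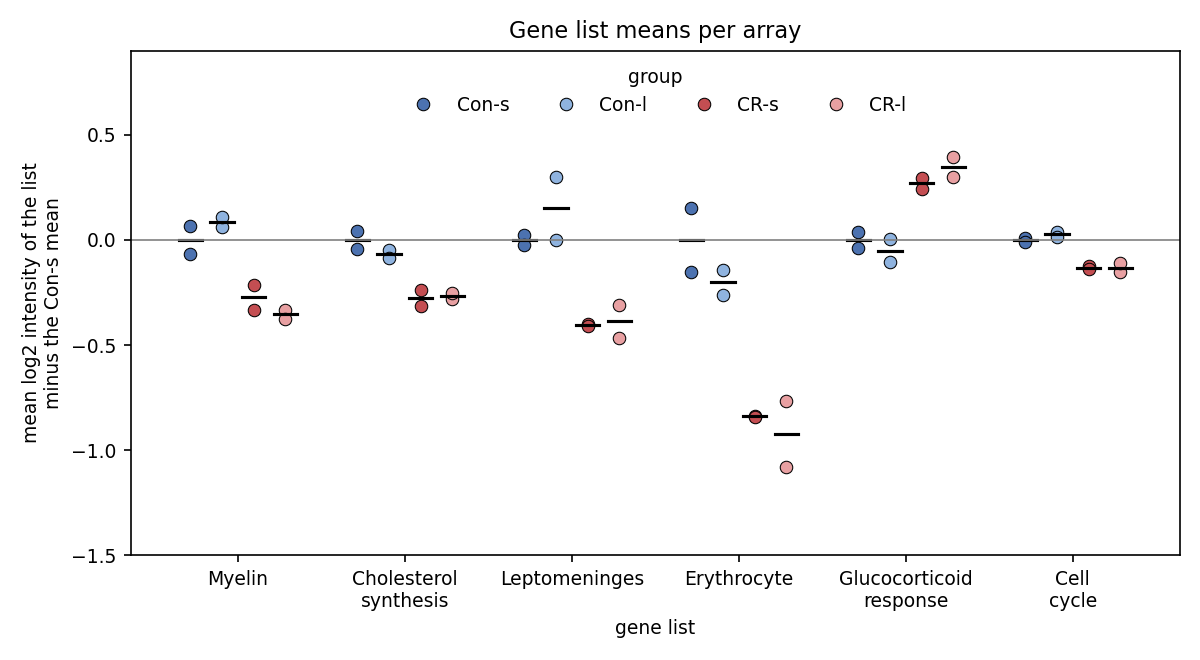
Mean log2 intensity of 6 gene lists in each array, relative to the Con-s mean, with group means as lines (n = 2). In the myelin, cholesterol, meningeal, red blood cell and cell cycle lists all 4 CR arrays lay below all 4 Con arrays, and in the glucocorticoid list above them.

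The remaining lists without a call in the averaged diet comparison had these adjusted p: thyroid hormone response 0.0616 (mean -0.07), monoamines 0.0616 (mean 0.10), astrocytes 0.0741 (mean -0.13), ribosomal proteins 0.115, GABA synapse 0.232 and glutamate synapse 0.232. Striatal neurons had 0.408, releasing and magnocellular hormones 0.408, immediate early genes 0.453, energy sensing 0.456, immature neurons 0.456 and MHC class I 0.456. The IGF axis had 0.463, leptin signalling 0.697, thalamic neurons 0.711, cortical and hippocampal neurons 0.726, microglia 0.764 and glycolysis 0.785. The respiratory chain had 0.833, chromatin genes 0.86, ependyma and tanycytes 0.86 and pituitary 0.866. Members that passed over all genes within these lists were 1 in thyroid hormone response, 2 in astrocytes, 2 in the IGF axis, 1 in releasing and magnocellular hormones (Oxt) and 1 in microglia. The test pointed up beside a negative mean or median for the IGF axis (mean -0.02, median 0.05), pituitary (mean -0.06, median 0.03), thalamic neurons (median -0.04) and chromatin genes (median -0.02), and down beside a median of 0.00 for ependyma (mean -0.03). The Y-chromosome list had fewer than 5 measured genes and was not tested.

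In saline-treated offspring (CR-s against Con-s, 2 arrays each), the effect of restriction alone, Agrp measured 8.23 ± 0.09 (SD, n = 2) in CR-s and 7.52 ± 0.02 in Con-s, a log2 difference of 0.71 (SE 0.13, adjusted p = 0.267). Npy measured 9.86 ± 0.13 in CR-s and 9.38 ± 0.16 in Con-s, a difference of 0.48 (SE 0.13, adjusted p = 0.412). Oxt measured 11.02 ± 0.09 and 11.57 ± 0.18, a difference of -0.55 (SE 0.09, adjusted p = 0.255), Pomc differed by -0.21 (SE 0.07, adjusted p = 0.496) and Cartpt by -0.23 (SE 0.08, adjusted p = 0.508). None of these passed, nor did Stat3 (-0.19, adjusted p = 0.491) or any other gene. Among genes differing at least 1.5-fold the smallest p were those of Alox15 (-1.65, SE 0.20), Pvr (-1.05, SE 0.13), Enpp2 (-0.63, SE 0.08), Ptgds (-1.47, SE 0.19) and Erbb3 (-0.72, SE 0.09), each at an adjusted p of 0.176, and on the higher side Rbm3 (1.13, SE 0.14, adjusted p = 0.176), Ly6i (0.86), Fkbp5 (0.62) and F2rl2 (0.70). The other fixed genes lay between -0.12 (Pmch and Avp) and 0.18 (Trh), with Hcrt at -0.10, Crh at -0.04, Bdnf at 0.02, Mc3r at 0.04, Mc4r at 0.05 and Socs3 at 0.00. With limma 0 of 14506 genes passed, and 1233 had an unadjusted p under 0.05 (493 higher, 740 lower). With trend and robust settings 66 genes passed, and among the upper 60 percent by mean 16.

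Under saline 8 lists were called, and none with an estimated correlation, where the adjusted p was 0.281 for cell cycle, cholesterol, red blood cells and glucocorticoid response, 0.357 for myelin, 0.485 for vessels and meninges and 0.816 for striatum. All 21 myelin genes were lower (mean log2 -0.27, camera adjusted p = 1e-13), all 18 cholesterol genes (-0.28, adjusted p = 4.48e-16), all 8 red blood cell genes (-0.84, adjusted p = 1.28e-08), 14 of 15 meningeal genes (-0.40, adjusted p = 2.77e-09), 17 of 18 vessel genes (-0.13, adjusted p = 2.32e-05) and 12 of 17 cell cycle genes (-0.13, adjusted p = 0.000281). Of the glucocorticoid genes 16 of 17 were higher (0.27, adjusted p = 2.55e-09), and of the striatal neuron genes 13 of 14 (0.12, adjusted p = 0.0328), led by Pde10a (0.20) and Drd1 (0.24). No member passed over all genes. Adjusted over the list alone 9 myelin, 13 cholesterol, 5 red blood cell, 6 meningeal, 3 vessel and 5 cell cycle genes were lower, and 6 glucocorticoid genes and 1 cell cycle gene (Aurkb) were higher. The striatal call ended without CR-s replicate A (mean 0.06, adjusted p = 0.33), Con-s replicate A or Con-s replicate B, and the other 7 lists were called without any single array.

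The effect of leptin in restricted offspring (CR-l against CR-s, 2 arrays each) bears on whether early leptin moves the energy-balance peptides of these animals. Npy measured 10.07 ± 0.24 (SD, n = 2) in CR-l, a log2 difference of 0.21 from CR-s (95% confidence interval -0.10 to 0.53, adjusted p = 0.823). Agrp measured 8.13 ± 0.27, a difference of -0.10 (interval -0.40 to 0.20, adjusted p = 0.907). Pomc differed by -0.09 (SE 0.07), Cartpt by -0.13 (SE 0.08), Oxt by 0.05 (SE 0.09) and Avp, the vasopressin gene, by 0.24 (SE 0.12), none of which passed. Socs3, the feedback inhibitor of leptin signalling, stood at -0.00 (SE 0.11), Stat3 at 0.10, Mc4r at 0.16, Mc3r at 0.01, Trh at -0.15, Pmch at -0.09, Hcrt at -0.08, Bdnf at -0.06 and Crh at 0.01. Among genes differing at least 1.5-fold the smallest p, all at an adjusted p of 0.808, were those of Retsat (-0.86, SE 0.12), Or2v2c (-0.63), Mug1 (-0.66), Pvr (0.79, SE 0.13), Ccdc107 (0.86, SE 0.15) and Apobec1 (0.63).

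With limma 0 genes passed in that comparison, and 849 had an unadjusted p under 0.05 (442 higher, 407 lower). The list of the growth hormone and IGF axis was called, with 14 of 16 genes higher (mean log2 0.12, camera adjusted p = 0.0403, adjusted p = 0.907 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone. Without a call, 10 of 12 thalamic neuron markers were higher (mean 0.22, adjusted p = 0.0867), as were 16 of 18 glutamate synapse genes (mean 0.10, adjusted p = 0.0802). Relative to the Con-s mean, the thalamic list lay at -0.22 on CR-s replicate B and 0.09 on CR-s replicate A, and at 0.35 and -0.04 on CR-l replicates A and B. Among the IGF axis genes the leading values were Igf1 (0.47, SE 0.19), Igfbp5 (0.36, SE 0.12), Insr (0.28, SE 0.09) and Igfbp3 (0.23, SE 0.07). A dimmer second probe set of Insr had 0.12. The call ended with cyclic loess (adjusted p = 0.0533), with the replicate letters as a block (adjusted p = 0.0604) and without CR-l replicate B, CR-s replicate B, Con-l replicate A or Con-l replicate B (adjusted p up to 0.233).

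In control offspring (Con-l against Con-s, 2 arrays each), the comparison asks what leptin does without restriction. Npy measured 9.04 ± 0.10 (SD, n = 2) in Con-l, a log2 difference of -0.34 (SE 0.13), Mc3r, a melanocortin receptor, differed by -0.38 (SE 0.14) and Oxt by -0.29 (SE 0.09), each at an adjusted p of 0.997. Agrp differed by -0.07, Pomc by -0.14, Cartpt by -0.17, Hcrt by -0.23, Pmch by -0.21, Trh by -0.13, Stat3 by -0.07, Socs3 by 0.06, Mc4r by 0.07, Avp by -0.04, Bdnf by -0.04 and Crh by -0.01. The smallest p was that of the translation factor gene Eif3i (-0.65, SE 0.07, adjusted p = 0.592), and among genes differing at least 1.5-fold the olfactory receptor gene Or1o11 came next (0.84, SE 0.12, adjusted p = 0.997). With limma 0 genes passed and 608 had an unadjusted p under 0.05, fewer than the 725 of chance.

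In these control animals 6 lists were called, all lost with an estimated correlation (adjusted p = 0.886 each). Meningeal genes were higher (14 of 15, mean log2 0.15, camera adjusted p = 0.0018), by 0.30 on Con-l replicate A and 0.00 on Con-l replicate B, as were myelin genes (19 of 21, 0.09, adjusted p = 0.00633) and immediate early genes (13 of 18, 0.07, adjusted p = 0.023), with values of 0.39 for Aldh1a2, 0.22 for Aspa and 0.35 for Nr4a1. Cholesterol genes were lower (14 of 18, -0.07, adjusted p = 0.00633), as were red blood cell genes (7 of 8, -0.20, adjusted p = 0.0214) and monoamine genes (15 of 19, -0.09, adjusted p = 0.0363), with values of -0.24 for Fdps, -0.27 for Epb42 and -0.21 for Hrh1. No member passed over all genes. Adjusted over the list alone 1 immediate early gene, Nr4a1, was higher. Con-l replicate A also lay above the other arrays in the pituitary (0.28) and striatal (0.26) lists. Each call ended without at least 1 array: meninges without Con-l replicate A (mean 0.00, adjusted p = 0.654), myelin without Con-s replicate A (0.02, adjusted p = 0.809) or Con-l replicate B, and immediate early genes without Con-l replicate A (0.03, adjusted p = 0.218) or Con-s replicate A. The same held for cholesterol (-0.03, adjusted p = 0.471) and red blood cells (-0.05, adjusted p = 0.554) without Con-s replicate B or without Con-l replicate B, and monoamines without Con-s replicate B (-0.03, adjusted p = 0.406), Con-l replicate B or either CR-s array. Larger means came without Con-l replicate B for meninges (0.30) and immediate early genes (0.11), without Con-s replicate B for myelin (0.15), and without Con-s replicate A for cholesterol (-0.11), red blood cells (-0.35) and monoamines (-0.15).

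Leptin-treated restricted offspring against saline-treated controls (CR-l against Con-s, 2 arrays each) show how far the treated animals stood from untreated controls. Rbm3 rose 3.08-fold (log2 1.62, SE 0.14) and Serpinh1, the collagen chaperone, fell 1.62-fold (log2 -0.70, SE 0.06), each with an adjusted p that rounds to 0.05 and lies under the threshold before rounding. Npy differed by 0.69 (SE 0.13, adjusted p = 0.154), Agrp by 0.61 (SE 0.13, adjusted p = 0.175), Oxt by -0.50 (SE 0.09, adjusted p = 0.139), Pomc by -0.30 (SE 0.07, adjusted p = 0.231) and Cartpt by -0.37 (SE 0.08, adjusted p = 0.206), none passing. Among genes differing at least 1.5-fold Enpp2 (-0.83), Alox15 (3.99-fold lower), Igfbp3 (0.60) and Abhd1 (-0.67) came next, without passing. At an unadjusted p under 0.05 there were 1772 genes. The count of 2 became 213 with trend and robust settings, 103 among the upper 60 percent by mean, 8 with array weights, and 0 with all probe sets or with the replicate letters as a block. Without Con-l replicate A or Con-l replicate B it was 1, and without any of the other 6 arrays 0.

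In that comparison 13 lists were called, and none with an estimated correlation (smallest adjusted p 0.27). Lower were myelin (20 of 21, mean log2 -0.35, camera adjusted p = 3.54e-15), cholesterol (17 of 18, -0.27, adjusted p = 7.19e-13), red blood cells (8 of 8, -0.92, adjusted p = 1.32e-08), meninges (15 of 15, -0.39, adjusted p = 2.27e-08), interferon response (17 of 19, -0.25, adjusted p = 0.00059), cell cycle (14 of 17, -0.13, adjusted p = 0.00235), ER stress (13 of 18, adjusted p = 0.00884), late-maturing neuron genes (12 of 14, adjusted p = 0.0156), vessels (10 of 18, adjusted p = 0.0242) and heat shock (8 of 10, adjusted p = 0.03). Higher were glucocorticoid response (17 of 17, 0.35, adjusted p = 9.5e-11), energy-balance receptors (15 of 20, 0.12, adjusted p = 0.0156) and glutamate synapse (15 of 18, 0.11, adjusted p = 0.0289). Beside the glutamate genes, all 12 markers of thalamic neurons were higher without a call (mean 0.15, adjusted p = 0.108). On CR-l replicate A, relative to the Con-s mean, the thalamic list lay at 0.35, the cortical and hippocampal list at 0.17 and the glutamate list at 0.15, and on CR-l replicate B at -0.04, -0.01 and 0.07. Leading values were -0.80 for Ndrg1, -0.55 for Msmo1, -0.57 for Ifitm3, -0.83 for Rsad2, 0.58 for Sgk1 and 0.42 for Npy1r. No member passed over all genes. Adjusted over the list alone 16 myelin, 13 cholesterol, 6 red blood cell, 8 meningeal, 3 interferon, 3 cell cycle, 5 ER stress, 3 vessel and 3 heat shock genes were lower, and 11 glucocorticoid, 2 receptor and 1 interferon gene were higher. Among the single arrays left out, Con-s replicate B alone ended the calls of receptors and late-maturing neurons. Those of vessels, ER stress, glutamate synapse and heat shock ended without that array and, separately, without at least 1 other (adjusted p up to 0.258 over all 6), that of heat shock also with cyclic loess (adjusted p = 0.0559). The receptor mean was 0.06 without Con-s replicate B and 0.18 without Con-s replicate A, and the glutamate mean 0.07 without CR-l replicate A. The other 7 were called without any single array.

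Under leptin the diet difference (CR-l against Con-l, 2 arrays each) passed for 3 genes. Rbm3 rose 3.19-fold (log2 1.67, SE 0.14), Enpp2 fell 1.87-fold (log2 -0.90, SE 0.08) and Serpinh1 fell 1.75-fold (log2 -0.81, SE 0.06), each at an adjusted p of 0.0339. Npy differed by 1.03 (SE 0.13, adjusted p = 0.0605) and Agrp by 0.68 (SE 0.13, adjusted p = 0.0983) without passing, Pomc by -0.16, Cartpt by -0.20 and Oxt by -0.21. Among the next by p, without passing, were Cdh19 (-1.36, adjusted p = 0.0513), Erbb3 (-0.89, adjusted p = 0.0535), Zbtb16 (0.88, adjusted p = 0.0605) and Hif3a (1.01, adjusted p = 0.0605). At an unadjusted p under 0.05 there were 2059 genes. The count of 3 became 469 with trend and robust settings, 249 among the upper 60 percent by mean, 24 with cyclic loess, 10 with array weights, and 0 with all probe sets, with these 2 groups alone or with the replicate letters as a block. It was 3 without CR-l replicate A, 2 without Con-l replicate B and 0 without any of the other 6 arrays.

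Under leptin 18 lists were called, none with an estimated correlation (smallest adjusted p 0.326). All 21 myelin genes were lower (mean log2 -0.44, camera adjusted p = 2.28e-19), Enpp2 passing over all genes and 21 adjusted over the list alone. Also lower were meninges (15 of 15, -0.54, adjusted p = 1.63e-12), cholesterol (17 of 18, -0.20, adjusted p = 1.4e-07), red blood cells (7 of 8, -0.72, adjusted p = 4.65e-05), cell cycle (15 of 17, adjusted p = 0.000791), vessels (adjusted p = 0.0138), late-maturing neurons (adjusted p = 0.0138), heat shock (adjusted p = 0.0214), immediate early genes (adjusted p = 0.0227), ER stress (adjusted p = 0.0243), precursors of oligodendrocytes (adjusted p = 0.0446) and interferon response (adjusted p = 0.0446). Higher were glucocorticoid response (16 of 17, 0.40, adjusted p = 9.45e-12), energy-balance receptors (18 of 20, 0.17, adjusted p = 0.00032), hypothalamic transcription factors (19 of 20, 0.11, adjusted p = 0.00186), circadian clock (11 of 14, 0.13, adjusted p = 0.00207), ribosomal proteins (17 of 27, adjusted p = 0.0446) and monoamines (13 of 19, adjusted p = 0.0481). Leading values were -0.63 for Ermn, -0.70 for Aldh1a2, 1.05 for Mt2A, 0.46 for Npy1r, 0.37 for the clock gene Per1 and 0.43 for the serotonin receptor gene Htr2a. Adjusted over the list alone 12 meningeal, 8 cholesterol, 5 red blood cell, 3 cell cycle, 3 vessel, 2 heat shock, 4 ER stress and 2 precursor genes were lower, and 12 glucocorticoid, 2 receptor, 3 clock, 2 monoamine and 1 cholesterol gene were higher. The myelin, meningeal, cholesterol, red blood cell, cell cycle, glucocorticoid, receptor and clock lists were called without any single array. The other 10 calls each ended without at least 1 of CR-l replicate A, CR-l replicate B, Con-l replicate A and Con-l replicate B (adjusted p up to 0.748), those of interferon, monoamine and ribosomal genes with cyclic loess (adjusted p of 0.0649, 0.0606 and 0.0788), and those of interferon and ribosomal genes with the replicate letters as a block (adjusted p of 0.0772 and 0.0624). Without Con-l replicate A the mean was -0.02 for interferon, -0.06 for vessels and -0.05 for immediate early genes. Without Con-l replicate B it was -0.27 for interferon, 0.07 for hypothalamic transcription factors, -0.09 for late-maturing neurons and 0.03 for ribosomal proteins. Without CR-l replicate A it was -0.05 for precursors and 0.19 for monoamines, and without CR-l replicate B -0.40 and 0.04.

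The interaction asked whether leptin acted differently in restricted and control offspring (8 arrays). Npy had a difference of 0.55 between the leptin effects (SE 0.19, adjusted p = 0.898) and Oxt of 0.34 (SE 0.13, adjusted p = 0.898), while Agrp had -0.03, Pomc 0.06 and Cartpt 0.03. None of these passed. The smallest p was that of the olfactory receptor gene Or5b104 (1.03, SE 0.10, adjusted p = 0.278), and among genes differing at least 1.5-fold Or5p59 (-0.61), Eif3i (0.65), Pvr (1.03) and Retsat (-0.89) were among the next, each at an adjusted p of 0.898. With limma 0 genes passed, and 747 had an unadjusted p under 0.05. By camera 7 lists were called, all lost with an estimated correlation (adjusted p = 0.817 each). The leptin effect was more positive in restricted offspring for receptors (17 of 20 genes, mean 0.14, adjusted p = 0.0144), glucocorticoid response (14 of 17, 0.13, adjusted p = 0.0271) and the IGF axis (10 of 16, 0.13, adjusted p = 0.0376). It was more negative for myelin (20 of 21, -0.16, adjusted p = 2e-04), immediate early genes (15 of 18, -0.11, adjusted p = 0.00941), meninges (15 of 15, -0.13, adjusted p = 0.0304) and pituitary (12 of 14, -0.25, adjusted p = 0.0304). Leading values were 0.46 for the NPY receptor gene Npy1r, 0.29 for Klf9, 0.34 for Insr (0.17 on its second probe set), -0.28 for Enpp2 and -0.35 for Junb. No member passed over all genes, and adjusted over the list alone 1 meningeal gene, Aldh1a2, was lower (-0.61, SE 0.14). In the pituitary list Cga alone had -1.76 (SE 1.13), beside a list median of -0.12. Without Con-l replicate A the meningeal mean turned to 0.02 (adjusted p = 0.921), the pituitary mean was -0.12 (adjusted p = 0.102) and the immediate early call ended (adjusted p = 0.102). Without Con-l replicate B the means were -0.28 for meninges, -0.37 for pituitary, 0.09 for receptors and 0.07 for glucocorticoid response. Without CR-s replicate B the myelin mean was -0.10 (adjusted p = 0.0526) and that of receptors 0.09, and without Con-s replicate A -0.10 (adjusted p = 0.0231) and 0.08. Without CR-l replicate A the meningeal mean was -0.06, and without CR-l replicate B -0.21, with glucocorticoid response at 0.08. With cyclic loess the pituitary and IGF calls ended (adjusted p of 0.13 and 0.0515).

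Averaged over both diets (4 arrays against 4), leptin left Npy at -0.06 (SE 0.10), Agrp at -0.08 (SE 0.09), Pomc at -0.11 (SE 0.05) and Cartpt at -0.15 (SE 0.06), the latter at an adjusted p of 0.913. With limma 0 genes passed, and 707 had an unadjusted p under 0.05. Adpgk (1.09, SE 0.34) and Grm2 (0.64, SE 0.22) led by p among genes differing at least 1.5-fold, both at an adjusted p of 0.913. By camera 7 lists were called, and none with an estimated correlation, where each had an adjusted p of 0.926. Higher were glutamate synapse (14 of 18, adjusted p = 0.0481), meninges (13 of 15, adjusted p = 0.0481) and oligodendrocyte precursors (10 of 11, adjusted p = 0.0481). Lower were red blood cells (6 of 8, adjusted p = 0.04), interferon response (16 of 19, adjusted p = 0.04), peptides raising food intake (10 of 12, adjusted p = 0.0481) and MHC class I (11 of 12, adjusted p = 0.0481). Beside the glutamate genes, 10 of 12 markers of thalamic neurons were higher without a call (mean 0.15, adjusted p = 0.0689). Leading values were 0.10 for the glutamate receptor gene Grin2b, 0.27 for Dcn, 0.12 for Pdgfra, -0.20 for Ifitm3, -0.15 for Pmch and -0.16 for Qrfp. None of their members passed over all genes or adjusted over the list alone. All 7 calls ended with cyclic loess, and the exact permutation test over the 35 splits gave an adjusted p of 1 for each. Without CR-s replicate A no list was called, without CR-s replicate B or Con-l replicate B 2, without Con-s replicate A 3, and without CR-l replicate B or Con-s replicate B 4. With the replicate letters as a block the glutamate and meningeal calls ended (adjusted p of 0.0542 each). The meningeal mean of 0.08 was 0.01 without Con-l replicate A, 0.05 without CR-l replicate B and 0.16 without Con-l replicate B. That of interferon genes was -0.16 without Con-l replicate A and -0.03 without Con-l replicate B. That of red blood cells was -0.22 without CR-l replicate A or Con-s replicate A and -0.07 without CR-l replicate B or Con-s replicate B. The precursor mean of 0.02 lay between -0.07 (without CR-l replicate B) and 0.11 (without CR-l replicate A). The peptide mean of -0.07 was -0.04 without Con-l replicate B and -0.05 without Con-s replicate A. The glutamate mean was 0.04 without CR-s replicate B and the MHC mean -0.05 without CR-l replicate B.

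Whether the diet effect remained under leptin was compared directly. Across all genes the diet differences under saline and under leptin, which share no array, correlated at 0.398, where simulated data without effects gave 0.00164, and 60.5% of genes had the same sign. Genes are not independent replicates, so these values carry no test. The leptin effects in control and restricted offspring correlated at 0.0229, with 50.4% of genes of the same sign. The covariance of the diet differences was 0.00861, and that between single-array estimates of the diet difference under saline was 0.00526 or 0.00321 depending on how the arrays were paired. The ratio was 2.04 (1.73 among the upper 60 percent by mean, 1.82 with cyclic loess), where an effect kept under leptin gives 1 and a lost effect 0. The part of the restriction effect that leptin opposed came to -0.626, with -0.333 and -0.920 for the single pairings, where full reversal gives 1 and none 0. Both ratios lie outside the range from 0 to 1. Their denominator comes from the saline arrays alone and varied with the pairing, so neither gives the size of a leptin effect. The plain correlation of CR-l minus CR-s with CR-s minus Con-s was -0.306, where shared arrays alone gave -0.5 in simulation. A diet effect adds variance and so brings this correlation nearer to 0, and the covariance itself, -0.00504, lay within the range of the simulation, -0.00581 to -0.00485.

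The 175 genes that passed in the averaged diet comparison, a set chosen after the data had been seen, all had the same sign under saline and under leptin, with a median difference of 0.35 under saline and 0.45 under leptin in the direction of the diet difference. Their choice by the average of these differences favours equal signs, so this is no test of whether the effect remained. Between CR-l and CR-s 128 of them differed further in that direction and 47 (26.9%) against it, with a median of 0.07 along the diet direction. Between Con-l and Con-s 58 differed along it and 117 against it (median -0.05), and the interaction of the 2 leptin effects had 137 along it and 38 against it (median 0.10). An exact permutation of 2 arrays against 2 cannot give a p under 0.333, so the p given is that of limma's fry, a rotation test: 0.0326 for CR-l against CR-s, 0.135 for Con-l against Con-s and 0.022 for the interaction. Fry asks whether the genes moved on balance in a direction and does not compare them with other genes. The 175 genes were chosen on these same arrays, in part for a small spread between replicates. Fry measures its error by that spread, so its p may be too small. Without CR-l replicate A the fry p for CR-l against CR-s was 0.0585, without CR-l replicate B 0.142, without CR-s replicate A 0.0794, without CR-s replicate B 0.134, without Con-l replicate A or Con-l replicate B 0.061, and with the replicate letters as a block 0.0664. Without Con-s replicate A or Con-s replicate B it was 0.0156, with cyclic loess 0.0299, and for the genes passing with trend and robust settings 0.0335.

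**Figure D3:**
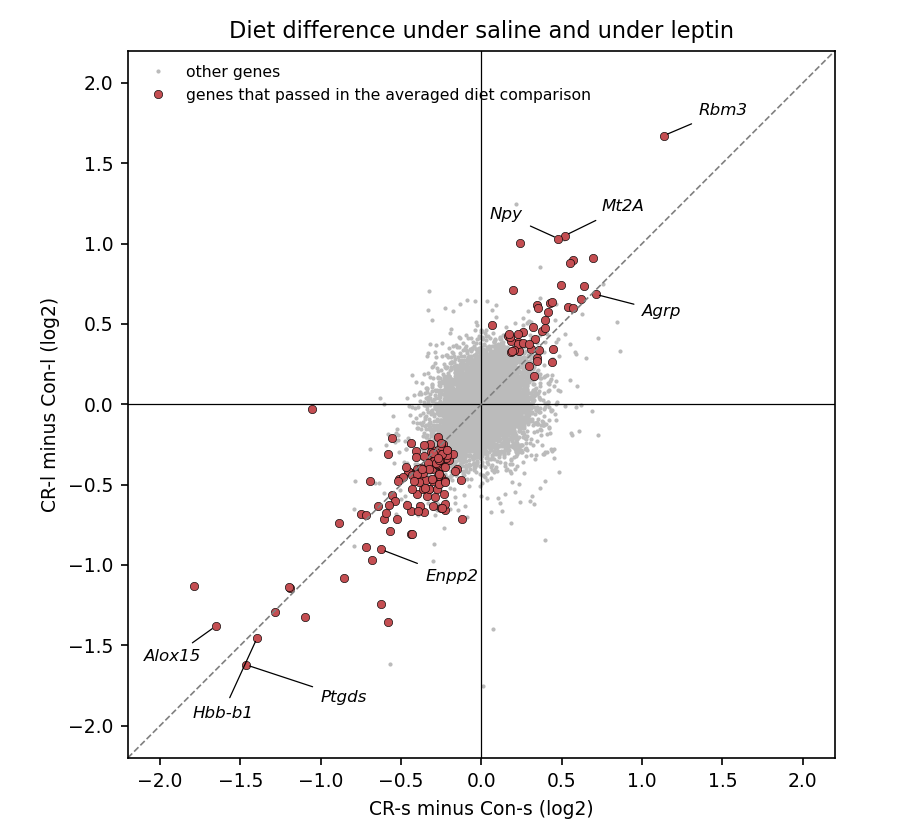
Log2 diet difference of each of 14506 genes under saline (horizontal axis) and under leptin (vertical axis), with the 175 genes that passed in the averaged comparison as larger points and equality as a dashed line. All 175 lie in the quadrants of equal sign, which their choice by the average favours.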

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

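The exact permutation test of lists and the signed test of the 175 diet genes were chosen only after the result was seen. The tests of explanations for the myelin, meningeal and leptin patterns were set after those patterns, but before their own results, were known.

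In 7 gene lists the mean leptin effect differed between the diets by camera's test of the interaction, and in none with an estimated correlation (adjusted p = 0.817 for each). The mean log2 difference was 0.1371 for energy-balance receptors (0.08 in restricted, -0.06 in control offspring), 0.1276 for glucocorticoid response (0.08 and -0.05) and 0.1314 for the IGF axis (0.12 and -0.01). It was -0.1141 for immediate early genes (-0.04 and 0.07), -0.1334 for meninges (0.02 and 0.15), -0.1642 for myelin (-0.08 and 0.09) and -0.2455 for pituitary (-0.10 and 0.15). Without 1 array these means ranged from 0.08 to 0.20 for receptors, 0.07 to 0.18 for glucocorticoid response, 0.10 to 0.16 for the IGF axis, -0.15 to -0.08 for immediate early genes, -0.28 to 0.02 for meninges (0.02 without Con-l replicate A), -0.23 to -0.10 for myelin and -0.37 to -0.12 for pituitary. The receptor call was then kept in 5 of 8 cases, glucocorticoid response in 4, the IGF axis in 4, immediate early genes in 7, meninges in 3, myelin in 7 and pituitary in 4. The pituitary value contains Cga, the shared subunit of pituitary glycoprotein hormones, at 9.19 on Con-l replicate A and between 5.83 and 6.19 on the other 7 arrays.

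The myelin difference of -0.1642 was weighed because myelin genes also carried the diet effect. The tables argue against neither technical explanation tested. Without CR-s replicate B, the array with the narrowest signal range, the adjusted p rose to 0.05257, just past the threshold, so a single array may decide the call. With the correlation between genes estimated from the data the adjusted p was 0.817. That setting ended all 75 list calls, also that of cell cycle in CR-s against Con-s, where the estimated correlation was negative (-0.055). There camera's unadjusted p rose from 4.91e-05 to 0.0119, since the setting also leaves the test only the residual degrees of freedom. The setting therefore cannot decide whether correlation between genes accounts for the myelin call. A real difference in the response of myelin genes to leptin stays open, untested by other samples.

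The lower myelin and cholesterol lists of restricted offspring are the second pattern. The narrow signal range of CR-s replicate B is argued against, since without that array the myelin list had an adjusted p of 2.613e-20 and the cholesterol list of 5.34e-13, both still lower, while with an estimated correlation and all arrays the adjusted p was 0.263 and 0.309. A smaller share of oligodendrocytes with no change per cell may lower all myelin genes alike. The 21 genes differed from each other by more than their standard errors (heterogeneity Q 173.7 on 20 degrees of freedom; p = 6e-05 from draws simulated with those errors, not an exact test), but all were lower, from -0.82 to -0.12. Since some of these genes are also expressed by other cells, cell share and expression per cell cannot be told apart, and delayed maturation under the restricted diet stays open.

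The lower meningeal list is the third pattern. Less meningeal tissue in the restricted samples is a candidate explanation. Its test found 13 of the 15 genes lower by 0.2 or more on the log2 scale, collagen genes such as Col1a2 among them. This count uses the same genes and arrays as the pattern, so it cannot tell tissue amount from a change per cell. Red blood cell and vessel genes were lower too, as given, the vessel genes by a much smaller mean amount. A loss of all tissue other than neural tissue cannot be told apart from less meningeal tissue alone. The choroid plexus list had a mean of -0.09256 and a median of -0.03, with Kcnj13 at -1.17 and Slc13a4 at -0.51 but Ttr at 0.04. All 4 CR arrays lay below all 4 Con arrays in that list too (-0.10 to -0.08 against -0.04 to 0.04, exact permutation p = 0.0286), while camera did not call it (adjusted p = 0.567). Since the mean of the choroid plexus list leaned on Kcnj13 and Slc13a4, this separation cannot decide on a wider loss. The labels do not describe how evenly the tissue was dissected, and a change within meningeal cells of restricted animals stays open.

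For the diet result the real split called 267 genes in a model with the compared factor alone and the highest other split 1. So 1 of 35 splits reached the real count, a share of 0.0286 and the smallest that 8 arrays allow. This argues against chance for the count of genes, but a share of that size cannot exclude it. The labels also do not state whether the arrays hold independent animals or litters. For lists the real split called 16 and the highest other 15, again 1 of 35, a narrow margin for the count of lists. For leptin this model called 0 genes and 0 lists in the real split, so all 35 splits had to reach that count and the split count decides nothing. The highest other split, with 267 genes and 16 lists, is the diet split itself. The 7 lists called for averaged leptin came from the model with 4 groups and were not tested by these splits.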

How the results depend on the processing

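The labels do not state whether the replicate letters pair the arrays. Deviations from the group means correlated across genes at only -0.061 to 0.109 between groups, which does not exclude a pairing. With the replicate block 87 genes passed in the averaged diet comparison, 0 in CR-l against Con-s and 0 in CR-l against Con-l, 0 lists were called in CR-l against CR-s, and the fry p of the 175 diet genes between CR-l and CR-s was 0.0664 (median unchanged at 0.071). The block leaves 3 residual degrees of freedom in place of 4, and otherwise the cause was not tested. With trend and robust settings 66 genes passed in CR-s against Con-s, 213 in CR-l against Con-s, 469 in CR-l against Con-l and 744 in the averaged diet comparison, and 7 lists were called in CR-l against CR-s, 15 in Con-l against Con-s and 13 in CR-s against Con-s; the cause was not tested. Among the upper 60 percent by mean, with fewer genes tested and more prior degrees of freedom (3.95), the counts were 16, 103, 249 and 609 in the same order. With all probe sets, more features and fewer prior degrees of freedom (2.64), the last 3 were 0. Array weights gave 8 in CR-l against Con-s and 10 in CR-l against Con-l, cyclic loess 24 in the latter, these 2 groups alone 0 there, and the compared factor alone 267 for diet; the cause was not tested. Cyclic loess called 0 lists in CR-l against CR-s and for averaged leptin. The estimated correlation called 0 lists in all 8 comparisons. This held also where the estimate was negative (-0.055 for cell cycle in CR-s against Con-s), so the loss of calls does not measure the role of correlation alone. Leaving out each array, with 3 residual degrees of freedom, gave 0 to 27 genes for diet, 0 to 3 in CR-l against Con-l, 0 to 1 in CR-l against Con-s, CR-l against CR-s, Con-l against Con-s, interaction and leptin, and 0 in CR-s against Con-s. Lists then ranged from 13 to 18 for diet, 13 to 18 in CR-l against Con-l, 10 to 15 in CR-l against Con-s, 7 to 10 in CR-s against Con-s, 0 to 7 in CR-l against CR-s, 3 to 11 in Con-l against Con-s, 3 to 9 for interaction and 0 to 7 for leptin, and the median of the diet genes between CR-l and CR-s from 0.055 to 0.086. The covariance ratios need both arrays of each saline group, and no array of any group was left out for them. Under their 2 alternatives the ratios moved by less than the spread of their pairings. Of 7069 alternative values for 483 gene values named by the rule, 0 reversed a call, 399 lost it, 238 gained it, and 99 without a call changed sign. Only 652 of the 7069, by the rounded adjusted p, belonged to a gene value that had a call to lose. The 399 losses are to be read against these 652, so most gene calls did not outlast the alternatives. No signal over background was given in the sources used here.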

Other observations

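The hypothesis on temperature in this part was set after the rise of Rbm3, but before its own result, was known. Genes of proliferating cells were lower in restricted offspring averaged over treatments: 15 of 17 (mean log2 -0.14, camera adjusted p = 4.95e-05, adjusted p = 0.263 with an estimated correlation), 3 passing over all genes, with 8 lower and 1 higher adjusted over the list alone. Top2a (-0.64, SE 0.11), Ccna2 (-0.43, SE 0.06) and Rrm2 (-0.43, SE 0.06), genes of DNA replication and mitosis, fell, while Aurkb stood at 0.68 (SE 0.15, adjusted p = 0.0948). Of the ER stress genes 13 of 18 were lower (mean -0.08, adjusted p = 0.0139, adjusted p = 0.514 with an estimated correlation), 1 passing over all genes and 4 adjusted over the list alone: Pdia4, a folding enzyme of the ER, fell (-0.32, SE 0.05), and Calr stood at -0.24. Interferon-induced genes were lower (16 of 19, mean -0.16, adjusted p = 0.0108, adjusted p = 0.525 with an estimated correlation), none passing over all genes and, adjusted over the list alone, 3 lower and 1 higher, with Ifitm3 at -0.37 and Rsad2 at -0.58. Genes of the perineuronal matrix and of maturation, the late-maturing neuron list, were lower (12 of 14, mean -0.11, camera adjusted p = 0.00667, adjusted p = 0.483 with an estimated correlation). Of these 0 passed over all genes and 2 adjusted over the list alone, with the perineuronal net gene Acan at -0.31 and Pvalb at -0.22. Without Con-l replicate A the ER stress and interferon calls ended (adjusted p of 0.0521 and 0.135, the interferon mean at -0.10), and without Con-l replicate B that of late-maturing neurons (0.0533).

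Circadian clock genes were higher (11 of 14, mean log2 0.09, camera adjusted p = 0.00546, adjusted p = 0.54 with an estimated correlation), none passing over all genes and 4 adjusted over the list alone, led by Cry2 (0.24, SE 0.04, adjusted p = 0.0503), Per1 (0.25) and Per2 (0.25). Receptors of energy-balance hormones and peptides were higher (15 of 20, mean 0.10, adjusted p = 0.00667, adjusted p = 0.525 with an estimated correlation), none passing over all genes and 4 adjusted over the list alone, led by Igf1r (0.22), Hcrtr1 (0.33) and Cckbr (0.36). Both calls ended without CR-s replicate A (adjusted p of 0.107 and 0.0747). Hypothalamic transcription factors were higher in 19 of 20 genes by small amounts (mean 0.07, adjusted p = 0.00546, adjusted p = 0.474 with an estimated correlation), with none passing over all genes or adjusted over the list alone. Gfap, the astrocyte filament gene, fell 1.91-fold (-0.94, SE 0.12, adjusted p = 0.0233), while the astrocyte list as a whole was not called. Padi2, an oligodendrocyte enzyme, fell (-0.57, SE 0.05, adjusted p = 0.0116), Erbb3 fell (-0.80, SE 0.06, adjusted p = 0.0116), Serpinh1 fell (-0.62, SE 0.04, adjusted p = 0.00977) and Pnpla2, the triglyceride lipase, rose (0.46, SE 0.04, adjusted p = 0.0133).

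A hypothesis for Rbm3 is that restricted offspring had a lower brain temperature, since Rbm3 is induced by mild cold. Its test asked whether Cirbp, the other cold-induced RNA-binding protein, was higher and the heat shock list lower. Cirbp rose by 0.4014 on the log2 scale (SE 0.06, adjusted p = 0.0336), and 8 of 10 heat shock genes were lower (mean -0.14, camera adjusted p = 0.013, adjusted p = 0.43 with an estimated correlation), 1 passing over all genes and 4 adjusted over the list alone, Chordc1 (-0.40, SE 0.07) among them. Both values go with the hypothesis, which may hold, but no temperature is given, and other responses to restriction stay open. The probe sets without a unique symbol, 13905 in number, gave 0 calls by limma in each of the 8 comparisons, with 1314 at an unadjusted p under 0.05 for averaged diet and 761 to 1274 in the other comparisons.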
